A study of Homo sapiens with 6 samples.

How the data were processed

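RNA had been extracted with Trizol from HaCaT cells 48 hours into the treatment, and 6 libraries were sequenced on an Illumina instrument, 3 from cells with the control small interfering RNA and M5 and 3 from cells with the one against eIF4E and M5. The deposited table holds whole-number counts per gene, which the authors made from reads trimmed with cutadapt 1.9, checked with FastQC and placed on GRCh38, per the labels. The aligner, the counting tool, the gene annotation and whether strand was used are not given in the sources used here. The same table holds FPKM values, which the authors computed from these counts by dividing by gene length and by the total of the library, as deposited. The ratio of count to FPKM of a gene was constant between libraries within 1% for 99.98% of 9940 genes with over 500 counts in each library. The table has 29176 genes, of which 28414 have an identifier in GENCODE v29, the annotation used here for gene type, position, transcript length and 3' UTRs.

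Library totals were between 71044961 and 74246501 counts. A floor of 3 counts, the upper limit that a count of 0 allows, corresponds to between 0.040 and 0.043 CPM. Replicates of a group differed by more than counting error (chi-squared per degree of freedom between 21.3 and 25.7 over pairs), so none is a copy of another. The common biological coefficient of variation was 17.4%. The first principal component held 31.6% of the variance and separated the groups, and the second held 18.6%.

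Counts were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr with its minimum of 10 counts, which kept 18022 genes, TMM scaling with factors between 0.98 and 1.04, quasi-likelihood fit and two-sided test, 4 residual degrees of freedom before moderation). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Levels are given as TMM-scaled CPM, as mean ± SD over 3 libraries, and fold changes as log2 of si-eIF4E+M5 over si-NC+M5 with their SE. In total 38 gene lists were tested with camera from limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists, at least 3 tested members), with camera with an estimated correlation and with fry. Of these, 15 were called with the preset correlation, 9 higher and 6 lower, 17 by fry and 0 with the estimated correlation, where 4 had an unadjusted p under 0.05. Of the lists that camera did not call, fry called p53 targets (fry adjusted p = 0.0014), eIF4E-sensitive (0.036) and NF-kappaB genes (0.041) lower. It called chemokines (0.021) and STAT3 targets (0.040) higher. The G1/S (0.38), cap-binding (0.067) and cholesterol synthesis (0.051) lists were called by camera and not by fry. The samples, the test, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule names EIF4E, EIF4E2 and EIF4E3, the 8 higher and 8 lower genes with the largest change among called genes without overlap between groups, with a mean FPKM of at least 5 in the higher group and a regular symbol, and up to 2 genes per direction in each list. Other genes are said to be chosen after their values were seen.

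On simulated counts of 18022 genes with 50 changed genes at each fold for this comparison, edgeR recovered 14% of 1.25-fold, 52% of 1.5-fold, 82% of 2-fold and 98% of 4-fold changes, with a false discovery share of 9.56%. The camera test gave an unadjusted p under 0.05 in 1 of 200 lists without change. The simulated genes varied independently, so this does not test lists of correlated genes, such as the G2/M list with an estimated correlation of 0.72.

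Alternatives were limma on log2(FPKM + 1), with 0.5 and 0.1 as other pseudocounts, no filter on low counts, a mean FPKM of at least 5, TPM, median ratio and quantile scaling, size factors and the Wald test of DESeq2 1.42.0, no abundance trend or a robust estimate in the spread, protein-coding genes only, stricter thresholds, the replicate number as a block, and each library left out. Fits without genes that overlap another on the same strand and without genes with GCCTAT in the 3' UTR, and the fit on log2(FPKM + 1), were chosen after seeing the data. KEGG terms of 10 to 300 tested genes, also added after the data were seen, were tested with camera.

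For short sequences, genes with a mean FPKM of at least 1 and an annotated 3' UTR of at least 50 nt were used (10087 genes, EIF4E left out after a first scan that included it, which changed no verdict). The log2 fold change was corrected for length and GC content of the 3' UTR, and the shift of carriers of each 7-mer and 6-mer was given as z, with bounds for 7-mers from 1000 permutations of the fold changes (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, figures with matplotlib 3.10.9).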

Results

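Gene expression was measured by RNA sequencing in HaCaT cells, an established line of spontaneously immortalized human keratinocytes. All 6 samples had been stimulated with M5, named in the series title as the stimulus that makes the cells a culture model of psoriasis. In the psoriasis literature M5 is a mixture of the cytokines IL-17A, IL-22, oncostatin M, IL-1α and TNF-α, though the labels do not list its components. A group of 3 samples had received a control small interfering RNA (si-NC+M5) and a group of 3 had received one against EIF4E (si-eIF4E+M5), and total RNA was taken after 48 hours. EIF4E encodes the protein that binds the 5' cap of messenger RNAs and starts cap-dependent translation. The deposited counts summed to 71044961, 71335405 and 74246501 in the control libraries and to 72094634, 73889969 and 73429787 in the knockdown libraries, and between 22680 and 23364 genes had at least 1 count. The labels do not say that the replicates came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical. No unstimulated or untransfected sample is part of the comparison, so every value compares stimulated cells with stimulated cells.

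The comparison asks what lower EIF4E does to the transcriptome of M5-stimulated keratinocytes. EIF4E (ENSG00000151247, minus strand of chromosome 4, 98871684 to 98930637 in GRCh38) was lower in all 3 knockdown libraries. Its normalised level was 50.9, 48.2 and 51.2 CPM (counts scaled to library size) in the control libraries and 21.005, 18.4 and 23.5 CPM in the knockdown libraries, from 3620, 3371 and 3751 counts against 1573, 1356 and 1724. The group means were 50.1 ± 1.65 and 20.996 ± 2.55 CPM (SD, n = 3), which leaves 41.9% of the control level (95% confidence interval 36.4 to 48.2%). The log2 fold change was -1.25 ± 0.09 (SE), with an adjusted p of 7.2e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A two-sided exact permutation test of this gene alone gave p = 0.1, the smallest value that 3 against 3 samples allow. The 2 paralogs of the same cap-binding family were measured as well. EIF4E2, which binds caps but does not promote translation in the same way, was slightly higher (log2 fold change 0.21 ± 0.06, adjusted p = 0.046 in edgeR). EIF4E3 had a log2 fold change of 0.34 ± 0.11 that did not pass (adjusted p = 0.065 in edgeR). EIF4EP2, a processed pseudogene on chromosome 17 that shares sequence with EIF4E and was chosen after its values were seen, was lower by a similar amount (-0.97 ± 0.14), and reads of the parent gene cannot be separated from its own in these counts.

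**Figure D1:**
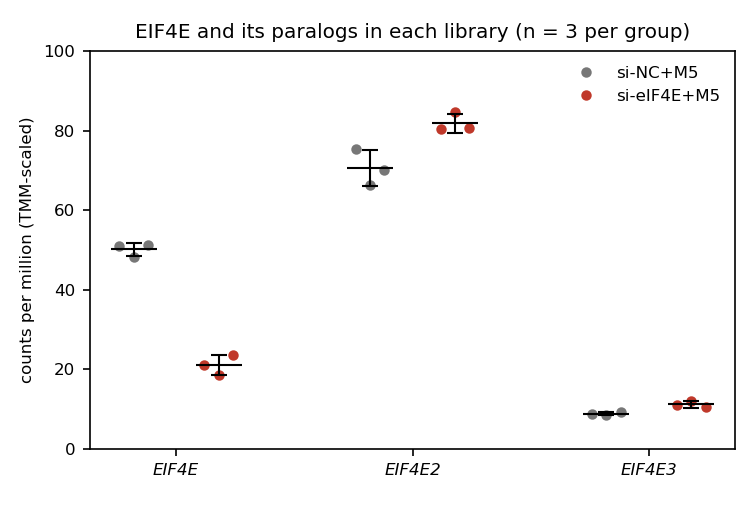
Normalised level (CPM) of EIF4E, EIF4E2 and EIF4E3 in each of the 6 libraries, with the group mean and SD (n = 3) as black lines. The knockdown libraries lie between 18.4 and 23.5 for EIF4E and the control libraries between 48.2 and 51.2.

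In the knockdown cells 44 of 49 tested genes of mitosis rose, while 27 of 32 genes that the stress-responsive transcription factor ATF4 controls and 22 of 33 genes that build ribosomes fell. Of 21 inflammatory cytokine genes 8 fell and 3 rose, and 19 of 45 genes of the interferon response and 7 of 20 of antigen presentation rose. These lists passed in camera with its preset correlation and none of them with an estimated correlation (smallest adjusted p = 0.40). Most of these shifts were moderate in size. In total 2853 of 18022 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1340 of them higher and 1513 lower, and 90.4% of them changed by less than 2-fold. At least a 2-fold rise was seen in 191 genes and at least a 2-fold fall in 83. The median absolute log2 fold change of the called genes was 0.42, and the median over all tested genes was -0.01. Groups did not overlap in 33.8% of the tested genes, where chance gives 10%. Of 127 genes named by the rule besides EIF4E, 28 lost their call in at least 1 of 22 other settings, mostly small changes and genes near the floor. These include EIF4E2, EIF4EBP2, CDC25B, RRM2, CX3CL1, CCL20, CD83, IFI44L, HLA-E, KRT17, SPRY4, COX4I1, XPO5, TARBP2, LAPTM5, CD68 and MT-ND3.

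Among well-expressed genes the largest rises were those of OR4C6 (log2 fold change 1.65 ± 0.15, SE, n = 3 per group here and below), an olfactory receptor gene, and of KIF20A (1.41 ± 0.15), a kinesin of the mitotic spindle. KRT15, a basal keratin, rose from 272 ± 17.4 to 640 ± 33.7 CPM (1.23 ± 0.07). H2AC8, SLC9A9, BIRC5, NUSAP1 and PCLAF followed, at 1.22, 1.21, 1.19, 1.18 and 1.18. The largest falls included CHAC1, a glutathione-degrading enzyme induced by ATF4 (-1.98 ± 0.19), and SERPINB2, the plasminogen activator inhibitor of keratinocytes (-1.98 ± 0.12), which went from 369 ± 65.4 to 93.8 ± 8.96 CPM. CSF2, encoding the cytokine GM-CSF, fell by 1.89 on the log2 scale and DKK1, a secreted Wnt antagonist, by 1.71. IGFL1 and FST, the activin antagonist follistatin, fell by 1.59 and 1.47. PRSS1 fell by 1.99, though close paralogs can share its reads. The readthrough gene TMEM189-UBE2V1 had 3835, 2421 and 492 counts in the control libraries and 0 in each knockdown library. It spans TMEM189 and UBE2V1, whose reads cannot be told from its own, and the summed level of the 3 genes was 366 CPM in the control group and 329 in the knockdown group. Its call was lost with a robust estimate of the spread (adjusted p = 0.13 in edgeR).

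**Figure D2:**
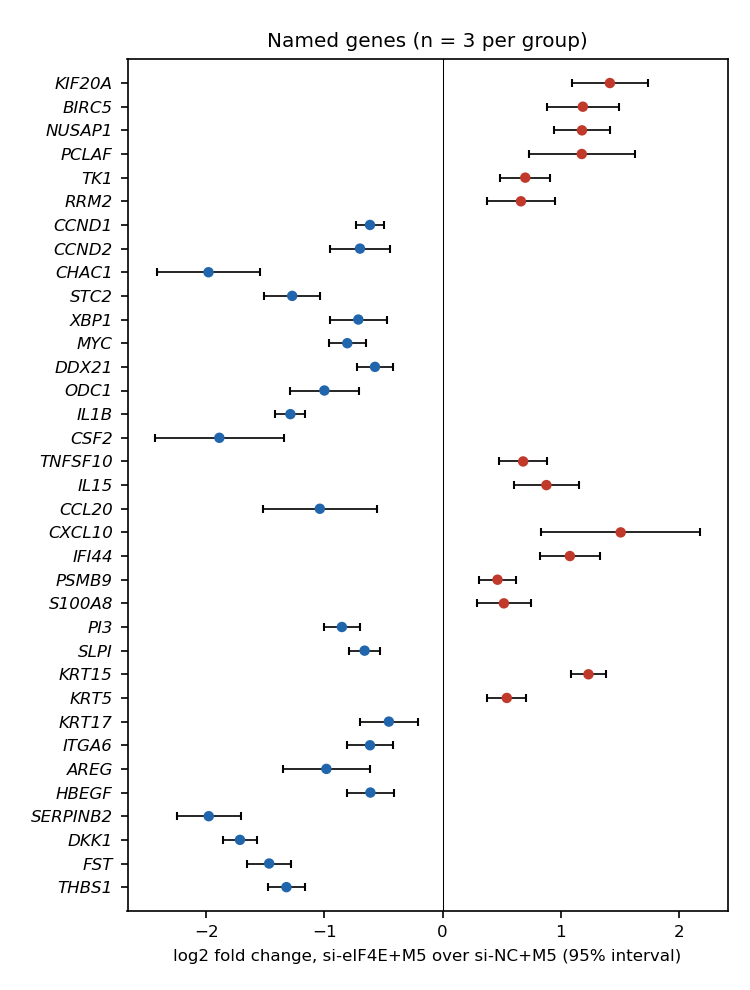
Log2 fold change of named genes, si-eIF4E+M5 over si-NC+M5, with 95% confidence intervals as bars (3 libraries per group). Mitotic genes such as KIF20A lie above 0 and CHAC1, IL1B and SERPINB2 lie below it.

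Most mitotic genes were called. Of 49 tested genes of the G2/M phase and mitosis, 44 rose, 1 fell and 4 did not pass (45 and 1 when adjusted over the list alone), with a median log2 fold change of 0.86 (camera adjusted p = 1.2e-41, and adjusted p = 0.40 with an estimated correlation). KIF20A rose from 14.4 ± 2.79 to 38.5 ± 5.16 CPM and BIRC5, the chromosomal passenger protein survivin, from 11.9 ± 2.32 to 27.1 ± 2.74 CPM. The phosphatase gene CDC25B was the member that fell (-0.22 ± 0.06). The G1/S and DNA replication genes were mixed, with 8 of 46 higher and 4 lower (9 and 4 when adjusted over the list alone) and a median of 0.14 (camera adjusted p = 0.043, and adjusted p = 0.79 with an estimated correlation). This call was lost under TPM scaling (adjusted p = 0.055 with the preset correlation), in 3 other settings and without any of 4 libraries in turn, and the median was 0.05 without si-NC+M5 replicate 2 and 0.22 without si-NC+M5 replicate 3. Thymidine kinase TK1 (0.70 ± 0.10) and the ribonucleotide reductase subunit RRM2 (0.66 ± 0.13) rose, and the cyclins CCND2 (-0.70 ± 0.12) and CCND1 (-0.61 ± 0.05) fell. Of 31 tested replication-dependent histone genes 3 rose and 0 fell, and the same 3 against 0 passed when adjusted over the list alone (median 0.16, camera adjusted p = 0.0054, and adjusted p = 0.53 with an estimated correlation). H2AC8 (1.22 ± 0.19) and H2BC5 (0.61 ± 0.08) were among them. The histone call was lost among genes of mean FPKM of at least 5 (adjusted p = 0.084 with the preset correlation). The histone median was 0.25 without si-NC+M5 replicate 1, 0.28 without si-NC+M5 replicate 2 and 0.24 without si-eIF4E+M5 replicate 3.

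Stress and ribosome-building genes moved the other way. Of 32 tested genes of the ATF4 and integrated stress response 27 fell and 0 rose, with the same counts when adjusted over the list alone, and the median was -0.57 (camera adjusted p = 5.6e-33, and adjusted p = 0.40 with an estimated correlation). CHAC1 fell from 26.0 ± 5.88 to 6.59 ± 1.57 CPM and STC2, a secreted glycoprotein, from 94.4 ± 13.7 to 39.1 ± 3.42 CPM. The ribosome biogenesis genes showed 22 of 33 lower and 0 higher (28 and 0 when adjusted over the list alone), with a median of -0.29 (camera adjusted p = 1.6e-15, and adjusted p = 0.40 with an estimated correlation). MYC, the transcription factor that drives this programme, fell from 437 ± 32.3 to 250 ± 13.96 CPM, and the nucleolar helicase DDX21 fell by 0.57 on the log2 scale. In the unfolded protein response list 6 of 25 genes fell and 0 rose (10 lower and 2 higher when adjusted over the list alone; median -0.11, camera adjusted p = 0.0073, and adjusted p = 0.56 with an estimated correlation). The sensor ERN1 (-0.75 ± 0.13) and its target XBP1 (-0.71 ± 0.11) were among the members that fell. That list's call and the next one's were both lost among genes of mean FPKM of at least 5 and without si-eIF4E+M5 replicate 1 (adjusted p = 0.061 and 0.067 with the preset correlation).

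Of 53 tested cap-binding and translation initiation factors 11 fell and 2 rose (13 and 4 when adjusted over the list alone), with a median of -0.09 (camera adjusted p = 0.0056, and adjusted p = 0.64 with an estimated correlation). The median was -0.05 without si-eIF4E+M5 replicate 1. Besides EIF4E itself, EIF5A fell from 632 ± 9.66 to 452 ± 18.3 CPM, while EIF4EBP2, a repressor that binds eIF4E, rose by 0.22 ± 0.06. The 79 cytosolic ribosomal protein genes gave 0 higher and 0 lower genes in edgeR and 0 when adjusted over the list alone, with a median of -0.0004. RPL7A and RPL8 had log2 fold changes of -0.02 ± 0.06 and -0.02 ± 0.06. Messenger RNAs described in the literature as eIF4E-sensitive, a description of their translation rather than of their amount, showed 10 of 30 lower and 4 higher (11 and 5 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.059, and adjusted p = 0.53 with an estimated correlation) but was called lower in some other settings (lowest adjusted p = 0.019 with the preset correlation, without si-eIF4E+M5 replicate 2). Ornithine decarboxylase ODC1 (-0.9996 ± 0.13) and MYC fell, and BIRC5 and RRM2 rose.

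**Figure D3:**
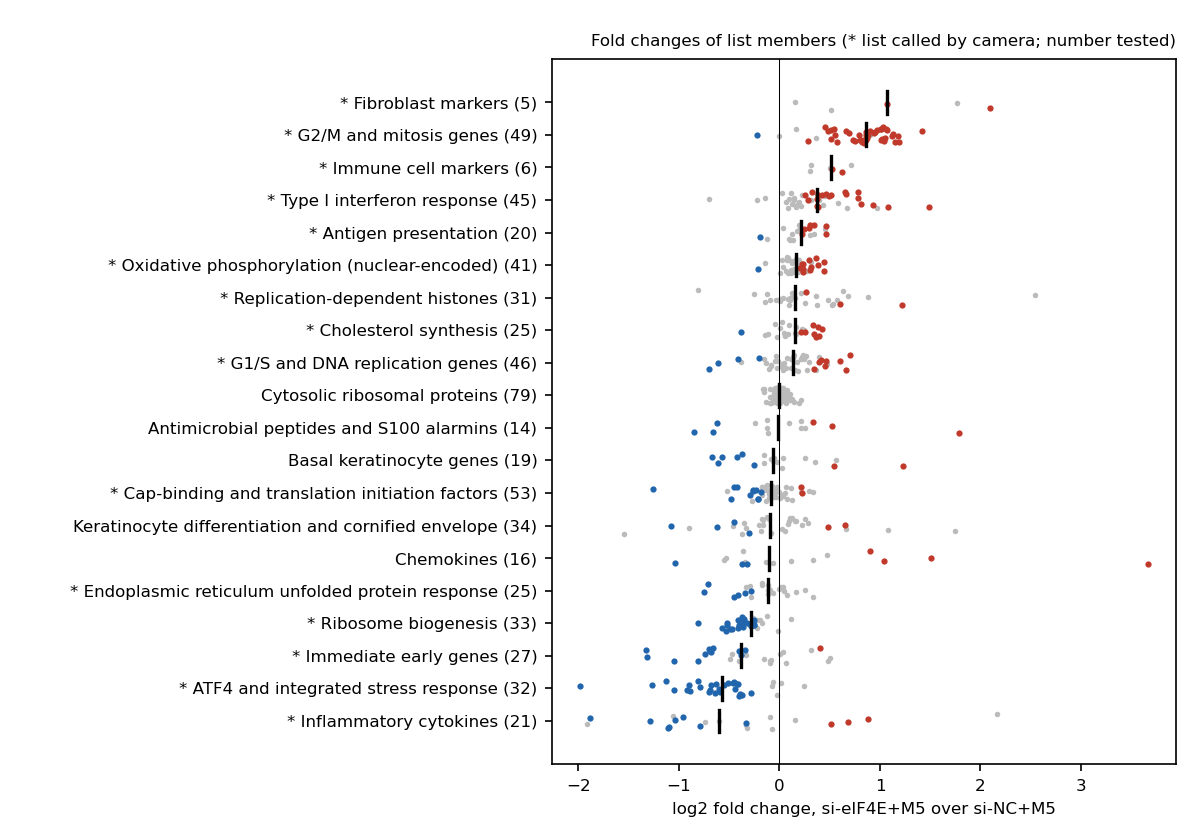
Log2 fold change of every tested member of 20 gene lists, si-eIF4E+M5 over si-NC+M5, with red and blue points for genes higher or lower at an adjusted p of 0.05, grey points for the rest and a black line at the list median. The G2/M list has its median at 0.86 and the ATF4 list at -0.57, and the cytosolic ribosomal proteins lie close to 0.

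Inflammatory genes went both ways. Of 21 tested inflammatory cytokine genes 8 fell and 3 rose (9 and 3 when adjusted over the list alone), with a median of -0.60 (camera adjusted p = 1.5e-05, and adjusted p = 0.40 with an estimated correlation). The median was -0.36 without si-NC+M5 replicate 2. IL1B, among the most abundant of them, fell from 467 ± 23.2 to 192 ± 2.53 CPM, and CSF2 from 4.84 ± 0.92 to 1.31 ± 0.34 CPM. The falls of IL1A (-1.10 ± 0.07), IL36G (-1.09 ± 0.12) and IL23A (-1.04 ± 0.31) were chosen after their values were seen. IL15 (0.88 ± 0.12) and TNFSF10, encoding the death ligand TRAIL (0.68 ± 0.09), rose. Of 16 chemokine genes 4 rose and 3 fell, with the same counts when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.53, and adjusted p = 0.67 with an estimated correlation). Its median was -0.10 (-0.13 to -0.01 with 1 library left out) and its mean 0.27. The fry test, which asks only whether the members move one way on balance, called it higher (adjusted p = 0.021). CXCL10 (1.51 ± 0.30) and, near the detection floor, CX3CL1 (3.66 ± 1.08) rose, and CCL20 (-1.04 ± 0.22) and CXCL16 (-0.37 ± 0.06) fell. NF-kappaB feedback and target genes gave 7 of 20 lower and 3 higher (8 and 4 when adjusted over the list alone; camera adjusted p = 0.11, and adjusted p = 0.53 with an estimated correlation). The NF-kappaB list was called lower in some other settings (lowest adjusted p = 0.018 with the preset correlation, without genes that carry GCCTAT, a 6-mer described below). TRAF1 (-0.67 ± 0.12) and CD83 (-0.64 ± 0.16) fell, and TNFAIP8 (0.49 ± 0.07) and the superoxide dismutase SOD2 (0.33 ± 0.07) rose. Among STAT3 feedback and target genes 5 of 20 were higher and 4 lower (6 and 5 when adjusted over the list alone; camera adjusted p = 0.47, and adjusted p = 0.64 with an estimated correlation), with SERPINA3 at 0.81 ± 0.14 and SOCS2 at -0.76 ± 0.09.

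Of 25 genes for M5 cytokine receptors and their signalling 4 rose and 4 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.97, and adjusted p = 0.99 with an estimated correlation). The receptor genes IL22RA1 (0.75 ± 0.15) and IL17RC (0.56 ± 0.10) rose, and the receptor gene IL1R1 (-1.81 ± 0.33) and the kinase gene MAP3K7 (-0.46 ± 0.07) fell. Interferon response genes were higher, with 19 of 45 up and 0 down (26 and 1 when adjusted over the list alone) and a median of 0.37 (camera adjusted p = 9.5e-11, and adjusted p = 0.40 with an estimated correlation). IFI44 rose from 8.54 ± 0.39 to 18.02 ± 2.13 CPM and IFI44L from 0.58 ± 0.21 to 1.63 ± 0.70 CPM. Antigen presentation genes gave 7 of 20 higher and 1 lower (12 and 1 when adjusted over the list alone), with a median of 0.21 (camera adjusted p = 1.7e-04, and adjusted p = 0.53 with an estimated correlation). HLA-DRB1 (0.47 ± 0.10) and the immunoproteasome subunit PSMB9 (0.46 ± 0.07) rose, and HLA-E fell by 0.20 on the log2 scale. Antimicrobial peptides and S100 alarmins went both ways, with 3 of 14 higher and 3 lower (5 and 4 when adjusted over the list alone; camera adjusted p = 0.70, and adjusted p = 0.84 with an estimated correlation). The alarmin S100A8 rose from 32.6 ± 3.68 to 46.8 ± 4.82 CPM, and TCN1 rose by 1.79 ± 0.21. The protease inhibitors PI3 (elafin) and SLPI fell by 0.85 and 0.66.

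Most keratinocyte identity genes did not pass. Of 19 basal keratinocyte genes 2 rose, KRT15 and KRT5 (0.54 ± 0.07), and 6 fell (3 and 7 when adjusted over the list alone; camera adjusted p = 0.53, and adjusted p = 0.82 with an estimated correlation). The basal list was called lower only without genes overlapping on the same strand (adjusted p = 0.047 with the preset correlation). The integrin ITGA6 fell from 848 ± 61.1 to 554 ± 67.0 CPM. A list of keratins named for hyperproliferation gave 3 of 10 lower and 1 higher (4 and 1 when adjusted over the list alone; camera adjusted p = 0.059, and adjusted p = 0.62 with an estimated correlation). That list was called lower in several other settings, with an adjusted p of 0.0057 to 0.049 and a median of -0.25 to -0.21 against -0.22. KRT17 (-0.45 ± 0.11) and KRT18 (-0.45 ± 0.06) fell and KRT19 rose by 0.33 ± 0.06. KRT18 and KRT19 are keratins of simple epithelia, so the list as drawn up is not made of hyperproliferation keratins alone. Differentiation and cornified envelope genes gave 2 of 34 higher and 4 lower (2 and 5 when adjusted over the list alone; camera adjusted p = 0.56, and adjusted p = 0.79 with an estimated correlation), with KRT13 at 0.66 ± 0.06 and the lipoxygenase ALOXE3 at -1.08 ± 0.11. EGFR ligands and signalling genes gave 7 of 25 lower and 1 higher (9 and 1 when adjusted over the list alone; camera adjusted p = 0.059, and adjusted p = 0.64 with an estimated correlation), and the ligand AREG fell from 49.2 ± 11.4 to 24.9 ± 4.50 CPM and HBEGF by a log2 fold change of -0.61 ± 0.09. The EGFR list was called lower in some other settings (lowest adjusted p = 0.012 with the preset correlation, without si-eIF4E+M5 replicate 3). Its median was only -0.01, with 11 of 25 members above 0, and -0.07 to -0.003 in the settings that called it. Immediate early genes were lower, with 12 of 27 down and 1 up, and the same counts when adjusted over the list alone (median -0.38, camera adjusted p = 2.6e-07, and adjusted p = 0.47 with an estimated correlation). The phosphatase DUSP4 (-1.31 ± 0.18) and SPRY4 (-1.32 ± 0.32), both feedback inhibitors of the ERK pathway, fell, and KLF10 rose by 0.40 ± 0.08. Epithelial-mesenchymal and matrix genes gave 9 of 30 lower and 6 higher (10 and 6 when adjusted over the list alone; camera adjusted p = 0.23, and adjusted p = 0.64 with an estimated correlation). Thrombospondin THBS1 fell from 415 ± 31.6 to 166 ± 8.13 CPM and TGFB2 by a log2 fold change of -1.99 ± 0.22, while the integrin ITGB6 rose from 563 ± 16.9 to 1040 ± 43.5 CPM and tenascin TNC by 0.94 ± 0.11.

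Among metabolic lists, nuclear-encoded oxidative phosphorylation genes gave 12 of 41 higher and 1 lower (23 and 2 when adjusted over the list alone; median 0.17, camera adjusted p = 3.4e-06, and adjusted p = 0.61 with an estimated correlation), with NDUFA4 at 0.45 ± 0.06 and COX4I1 at -0.21 ± 0.06. Cholesterol synthesis genes gave 8 of 25 higher and 1 lower (9 and 1 when adjusted over the list alone; median 0.15, camera adjusted p = 0.0032, and adjusted p = 0.61 with an estimated correlation), with LSS at 0.42 ± 0.07 and MSMO1 at -0.38 ± 0.06. The camera test called no direction for fatty acid genes (5 of 28 higher, 6 lower), hypoxia and glycolysis genes (6 of 33 higher, 4 lower), NRF2 antioxidant genes (7 of 26 higher, 4 lower), autophagy and lysosome genes (6 of 34 higher, 3 lower) or PI3K, AKT and mTOR genes (2 of 34 higher, 3 lower). Within them the cystine transporter SLC7A11 fell from 181 ± 12.3 to 97.04 ± 4.90 CPM, EGLN3 rose by 0.90 ± 0.14, ELOVL7 fell by 1.30 and IRS2 by 0.78. Neither the p53 target genes (2 of 28 higher, 7 lower) nor the apoptosis regulators (7 of 27 higher, 4 lower) passed in camera (adjusted p = 0.062 and 0.21, and adjusted p = 0.40 and 0.66 with an estimated correlation). The p53 list was called lower by fry (adjusted p = 0.0014). Camera called it lower with the replicate number as a block (adjusted p = 0.046 with the preset correlation). GADD45A (-1.23 ± 0.09) and the survival gene BCL2L1 (-0.59 ± 0.07) fell, and DDB2 (0.65 ± 0.07) and APAF1 (0.69 ± 0.11) rose. When adjusted over each list alone the higher and lower counts were 5 and 8 for fatty acid, 7 and 6 for hypoxia, 9 and 5 for NRF2, 6 and 3 for autophagy, 2 and 3 for PI3K, 4 and 11 for p53 and 8 and 4 for apoptosis genes.

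Markers of other cell types and of RNA quality were examined beside these groups. Of 5 tested fibroblast markers 2 rose, COL3A1 (from 0.31 ± 0.14 to 1.34 ± 0.08 CPM) and COL1A1 (from 3.10 ± 0.47 to 6.51 ± 1.42 CPM), and 0 fell (3 and 0 when adjusted over the list alone; camera adjusted p = 0.0051, and adjusted p = 0.40 with an estimated correlation). Of 6 tested immune cell markers 2 rose, LAPTM5 (0.63 ± 0.14) and CD68 (0.52 ± 0.12), and 0 fell (3 and 0 when adjusted over the list alone; camera adjusted p = 0.034, and adjusted p = 0.48 with an estimated correlation). The immune marker call was lost without si-NC+M5 replicate 2, si-NC+M5 replicate 3 or si-eIF4E+M5 replicate 3 (adjusted p up to 0.11 with the preset correlation), and the fibroblast call with no filter on low counts (adjusted p = 0.11). None of the 5 melanocyte or 5 endothelial markers passed in edgeR, nor when adjusted over the list alone. Of 13 mitochondrially encoded genes MT-ND3 rose (0.26 ± 0.07) and 0 fell, with 0 passing when adjusted over the list alone, and these genes held between 4.93 and 5.38% of the counts in every library. Of 14 genes of the small interfering RNA machinery XPO5 (-0.26 ± 0.07) and TARBP2 (-0.22 ± 0.06) fell and 0 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.43, and adjusted p = 0.79 with an estimated correlation).

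Lower genes were richer in a short sequence that also occurs in EIF4E. Among 10087 protein-coding genes with a mean FPKM of at least 1 and an annotated 3' UTR, the 6-mer GCCTAT lay in the 3' UTR of 530 of 1360 lower genes (39.0%), 1387 of 7656 genes that did not pass (18.1%) and 135 of 1071 higher genes (12.6%). The 6-mer was chosen after the fold changes were seen, as the one of 4096 whose carriers were lowest, so these shares describe it and are not a test. The share of lower genes was 10.3% of genes with no copy, 23.1% with 1 copy, 34.8% with 2 copies and 39.0% with 3 or more. None of these shares is corrected for the length or GC content of the 3' UTR, and longer 3' UTRs can hold more copies. EIF4E holds the 6-mer in its coding sequence on chromosome 4 at 98887176 to 98887181 (GRCh38), as AGCCTAT, and at 98876526 to 98876531 and 98871892 to 98871897 in the 3' UTR of its longest transcript, as TGCCTAT. That transcript is 11523 nt long, so it can hold many of the 4096 6-mers by chance. Finding GCCTAT in it therefore does not by itself link the 6-mer to the small interfering RNA. Of the lower genes given above, SERPINB2, DKK1, STC2, DDX21, ERN1, CCND2, CDC25B, EIF5A, TRAF1, SLPI, ITGA6, MAP3K7, HLA-E, IRS2, ELOVL7, COX4I1 and XPO5 carry it in the 3' UTR, and so do the higher genes EIF4E2, SLC9A9, SOD2, LSS and TNFAIP8. Without the genes that carry it, 2013 of 15970 genes passed, 1031 higher and 982 lower.

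**Figure D4:**
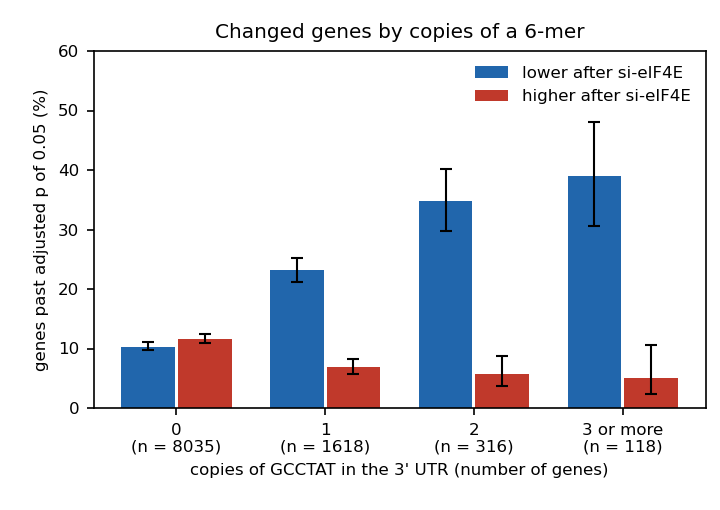
Share of protein-coding genes (percent) that were lower (blue) or higher (red) in si-eIF4E+M5 at an adjusted p of 0.05, by the number of copies of GCCTAT in the annotated 3' UTR, with 95% Wilson intervals over genes as bars. The lower share is 10.3% with no copy and 39.0% with 3 or more. The shares are not corrected for the length of the 3' UTR.

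Counts of called genes depended on single libraries, since 1598 genes passed without si-NC+M5 replicate 2 (724 higher, 874 lower). Because strand-specific counting is not stated, KIF20A, NUSAP1, DKK1, CCND1, CCND2, ITGA6, EIF5A, SOD2 and other genes that overlap a neighbour on the opposite strand may hold shared reads. Whether or not strand was used, so may genes that overlap one on the same strand, among them SERPINB2, KRT15, SLC9A9, PCLAF, PSMB9 and THBS1.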

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

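The fits on log2(FPKM + 1), without genes overlapping on the same strand and without genes with GCCTAT in the 3' UTR were chosen after seeing the data. EIF4E stayed lower and called in every setting that gave a value, with a log2 fold change of -1.35 to -1.17 with 1 library left out and -1.27 to -0.84 in the others, and it fell under the filter of a mean FPKM of at least 5. Of the main 2853 changed genes (1340 higher, 1513 lower), 1818 (801 higher) were left with no filter on low counts, where more genes are tested. A 2-fold minimum left 274 (191 higher, 83 lower) and an adjusted p under 0.01 left 1300 (573 higher, 727 lower). Without genes with GCCTAT in the 3' UTR, where fewer genes are tested, 2013 changed (982 lower). With 1 library left out, and so fewer samples, between 1598 and 2283 genes changed, 724 to 1168 higher and 874 to 1191 lower. The lowest counts came without si-NC+M5 replicate 2. The count of lower genes was 1001 without si-eIF4E+M5 replicate 1, and that of higher genes 889 without si-eIF4E+M5 replicate 2 and 848 without si-eIF4E+M5 replicate 3. The other counts stayed within 1.5 times, and the most, 3586, came with the DESeq2 Wald test. Its false discovery share was 25.5% on simulated counts, where far fewer genes changed than were called here.

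The replicate number as a block gave 3414 changed genes (1586 higher, 1828 lower) and 20 called lists, 5 of them new. Deviations of log CPM from the group mean correlated at 0.030, 0.032 and 0.044 between same-numbered samples, too low to treat them as pairs. Even so, the deviations of every sample correlated best with those of its own number in the other group, a hint from the data and not the design. No named gene gained or lost a call with the block.

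Of 127 named genes besides EIF4E, 28 lost their call somewhere, 25 of them with a library left out and 20 with no filter, and 1, EIF4E3, gained one. None reversed. All 15 called lists lost their call with an estimated correlation. Apart from that, 19 list calls were lost, 9 of them with a library left out, in the G1/S, cap-binding, unfolded protein response, fibroblast, immune cell and histone lists. The 22 gained were all lower, in hyperproliferation keratins (8), eIF4E-sensitive (5), EGFR (4), NF-kappaB (3), basal (1) and p53 (1) lists, and 5 of them came with the block. Uncalled results that changed sign without a call on either side are counted as unchanged, and the cause was not tested where none is given. On simulated counts with 50 changed genes at each fold, 52% of 1.5-fold changes were recovered. Far more genes were called in the data, which makes the adjusted p less strict, so this share does not carry over. The median absolute log2 fold change of the called genes was 0.42. How many changes under 1.5-fold were missed in the data is not known.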

Other observations

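The KEGG terms, the test of base composition and the test of G1/S against G2/M genes were chosen after the results were seen. Of 304 KEGG terms 29 passed in camera, 15 higher and 14 lower, and 0 with an estimated correlation (adjusted p = 0.97 for each of the 29). Genes of aminoacyl-tRNA synthesis were lower (12 of 44, 0 higher; adjusted p = 0.0014 in camera with its preset correlation), among them IARS1, which went from 650 ± 41.7 to 415 ± 28.2 CPM, and GARS1 (log2 fold change -0.62 ± 0.08). In RNA transport 25 of 148 genes were lower and 7 higher, with GEMIN5 at -0.90 ± 0.09 and the tRNA exporter XPOT at -0.68 ± 0.07. EIF4E, the target of the small interfering RNA, is counted among the lower genes of this term and had the largest fall (-1.25 ± 0.09). In NF-kappaB signalling 17 of 77 were lower and 2 higher (adjusted p = 0.015 in camera with its preset correlation). The smaller NF-kappaB list above did not pass in camera. In TGF-beta signalling 18 of 66 were lower and 2 higher, and INHBA, a subunit of activin, was at -1.07 ± 0.16 beside its antagonist FST. The glutamate dehydrogenase GLUD1 (-0.83 ± 0.06) and the transaminase GPT2 (-0.68 ± 0.06) fell in the term for arginine synthesis, 5 of 16 lower and 1 higher.

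The higher terms included immune and disease terms that share HLA genes, such as allograft rejection (7 of 20 higher, 1 lower), terms for neurodegeneration such as Parkinson disease (25 of 125 higher, 5 lower), and metabolic terms. NDUFA4 belongs to the Parkinson, Huntington and Alzheimer disease terms and to oxidative phosphorylation, so these terms are not separate either. In the citrate cycle 6 of 28 genes rose and 1 fell, with IDH2 at 0.52 ± 0.11. Peroxisomal genes gave 17 of 72 higher and 5 lower (EPHX2 0.72 ± 0.12, PXMP4 0.59 ± 0.09), and xenobiotic metabolism 8 of 34 higher and 0 lower (ALDH3B2 0.96 ± 0.14, ALDH3A1 0.76 ± 0.11). Complement genes C1R (0.82 ± 0.09), CFI (0.75 ± 0.07) and C5 (0.59 ± 0.13) rose within a term named for Staphylococcus aureus infection, where 9 of 34 genes were higher and 1 lower. The term for complement and coagulation cascades did not pass (8 of 45 higher, 6 lower; adjusted p = 0.68 in camera with its preset correlation). These genes were named after their values were seen.

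The number of changed genes was 2853 for the real groups and at most 2 in the other splits of the 6 samples, so 1 of 10 splits gave as many. The 10 splits are too few for a share under 0.05.

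The G2/M genes rose with a median of 0.86. The median was 0.87 to 0.88 under 3 other scalings and 0.73 with quantile scaling (fitted by limma on log2(FPKM + 1), which alone gave 0.74). The scalings hardly differed, with a median over all genes of -0.006 in the main fit and 0.013 with TPM scaling. They could therefore not have removed the rise and do not test scaling as its cause. What they show is a rise relative to the other genes. GC content and transcript length as the whole cause are argued against by 0.84 after a loess correction (the trend over all genes was small, with a median absolute shift of 0.019), and a single library by at least 0.78 with each left out. More cycling cells in all phases alike might raise G1/S genes as much, a premise that was not tested. The G2/M median lay 0.73 above the G1/S median (permutation of genes between the lists, p = 1e-05, the smallest that 100000 permutations give, where genes are not independent replicates). Both medians had been seen when this test was chosen, so it describes their difference. It cannot exclude more cycling cells, as the G1/S list mixes falling genes (CCND1, CCND2) with rising ones (TK1, RRM2). With 1 library left out the G2/M median stayed between 0.78 and 1.02 and the G1/S median between 0.05 and 0.22. What raised these genes stays open, and an effect of either siRNA other than the loss of eIF4E was not tested for this list, beyond its 4 carriers of GCCTAT among 48 searched members.

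The ATF4 and ribosome biogenesis lists together had a median of -0.41. It was nearest 0 of 4 scalings at -0.35 with the quantile fit, which also changes the test to limma on log2(FPKM + 1), and was -0.41 after the correction for GC content and length. Of 63 searched members 3 carry AGCCTAT, the 7-mer of EIF4E whose carriers were lowest over all genes, and the median of the others was -0.41. GCCTAT is carried by 4 of 30 ATF4 and 5 of 33 ribosome biogenesis members, with medians of -0.53 and -0.29 without them, so both counts argue against direct seed pairing with the members as the whole cause. The transcripts of ATF4 (-0.38 ± 0.06, named after its values were seen) and MYC (-0.81 ± 0.07) fell too, but whether this bears on the lists was not tested, and indirect effects of other siRNA targets stay open.

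Genes with GCCTAT in the 3' UTR were lower, with the lowest z of 4096 6-mers (-13.27) and AGCCTAT the lowest of 16145 7-mers (z -9.63, against a permutation bound of -4.49). Base composition is argued against by other 6-mers of the same bases, of which the lowest z was -2.84. This leaves out 6-mers that overlap GCCTAT in all but a single base. Among these TGCCTA, also of the same bases, had a z of -6.43, and it shares GCCTA with GCCTAT. Seed pairing of the siRNA predicts a smaller drop for genes with the 6-mer in the coding sequence only, and this was -0.042 against -0.12 for the 3' UTR, uncorrected for coding length. This is consistent with a microRNA-like effect of the siRNA against EIF4E, whose sequence is not given in the sources used here, and EIF4E holds AGCCTAT in its coding sequence, although its longest transcript holds 6776 of the 7-mers. For single carriers such as DKK1 and SERPINB2 such an effect and the loss of eIF4E were not separated, and a second siRNA with another seed would do so.

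In the same scan TGCCTAT followed AGCCTAT at a z of -9.40. GCCTATT (-9.21) and GCCTATA (-8.69), which are not in the longest EIF4E transcript, were nearly as low. At the other end TCGGAGA, which is not in the EIF4E transcript, was highest with a z of 5.33 in 216 genes, against a permutation bound of 4.53, and no explanation of it was tested. An effect of the control siRNA on its carriers in the control group, which would make them look higher in the knockdown group, stays open, as it does for other genes that rose.

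A further hypothesis was lower expression of YAP targets, raised by AMOTL2, F3, AXL, IGFBP3, GADD45A and CCN1 among the lower genes, while CCN2, also a known target, was near the floor and did not pass (0.32 ± 1.23). Of the 14 members of a published 22-gene signature not looked at before, 5 were lower and 1 higher, with a median of -0.24 (camera p = 1.2e-04 with the preset correlation and 0.052 with an estimated correlation). ANKRD1 went from 7.55 ± 1.29 to 1.08 ± 0.22 CPM, and 1 of the 14 carries GCCTAT, without which the median was -0.26. The result fits the hypothesis with the preset correlation only, the YAP1 transcript did not pass (-0.10 ± 0.06, looked at afterwards), and YAP protein and its activity were not measured.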
